A study of Mus musculus with 12 samples.

How the data were processed

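H3K9me2, a histone mark of repressed chromatin, was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) in the prefrontal cortex of wild-type (WT) mice, mice with familial Alzheimer's disease mutations (FAD) and FAD mice given BIX01294, an inhibitor of the histone methyltransferases EHMT1 and EHMT2 (FAD-BIX). Each of the 3 groups had 2 mice, and each mouse gave 1 ChIP library and 1 input library, so that 12 libraries were used. Per the labels' protocols, tissue punches were cross-linked in 1% formaldehyde for 12 min, and reads were either 50 bp single-end or 150 bp paired-end. Which library had which read type is not given in the sources used here. Per the submitters' processing notes, FastQC, Trimmomatic, BWA 0.7.12 and MACS2 2.1.0 were used, and the notes name the genome build mm9.

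The authors deposited 2 comparison tables, 1 for FAD against WT and 1 for FAD-BIX against FAD. Per the file headers, the deposited count columns hold the reads of each library in each region, and the deposited marks of which library a region was called in accompany them. RPM are reads scaled to the library total. The deposited RPM values equalled the count plus 1, times a constant of the library, and the inverse of that constant was taken as the library's total reads. The deposited fold enrichment, a ratio, equalled the RPM of the ChIP library over that of the input of the same mouse. The authors' log2 fold change equalled the log2 ratio of the mean fold enrichments of the groups. The deposited p-value equalled that of an unequal-variance test on the fold enrichments, and the deposited q-value was 1 in every row. These formulas were checked on every region, with a largest relative deviation of 4.75e-06. The regions were called in each library separately and then joined, so a region's presence in a table depends on the same reads that are then compared.

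The tables held 34413 and 44428 rows, which were reduced to 33787 and 43680 regions by keeping 1 row per region. A region was given the named gene it overlapped, or otherwise the named gene with the closest transcription start, which gave 37.6% and 37.9% of the regions a gene. Coordinates are those of the files. Although the notes name mm9, 99.7% of the genes matched by symbol in each table (3517 and 4010 genes) overlapped the position of the same gene in the RefSeq annotation of GRCm38.p6, and coordinates are therefore given as GRCm38. Whether the first base is counted as 0 or 1 is not given in the sources used here.

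ChIP counts of the 2 groups of each table were tested with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, TMM scaling, default filter on low counts, no replicate block), with Benjamini-Hochberg adjustment and a threshold of 0.05. The SE of a log2 fold is its absolute value over the square root of the F statistic of that test. It uses variation shared across regions and is not the spread of the mice of a group alone. The group ages are 5 to 6 months per the labels. Gene lists were tested with camera in limma 3.58.1 on the mean log2 normalised counts over each gene's regions (prior count 2), with a preset correlation of 0.01 and then an estimated one. Of 20 lists fixed before the data were examined, those with at least 3 genes were tested. Regions of the tables were matched at 50% reciprocal overlap, and 20 simulated data sets of unchanged groups sharing the FAD libraries gave the correlation that shared libraries cause. The simulation draws counts for the matched regions and does not repeat their selection. Distributions were compared with Fisher's exact test in SciPy 1.17.1. The steps were tested on simulated data with 200 regions changed by known folds.

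Total library reads were 20.45 to 26.58 M in ChIP and 13.92 to 23.76 M in input libraries. Between 2.00% and 4.23% of ChIP reads fell in the regions of a table, with a median of 11 to 20 reads per region, so counting error alone is large for most regions. All scalings used were relative, so a change shared by the whole genome could not be seen in either comparison. The alternatives were DESeq2 1.42.0 as a tool, its size factors or library totals as scaling, no filter on low counts, a replicate block, each ChIP library left out (with TMM and with library totals), ChIP over input in limma, stricter thresholds, autosomes, wider regions, and other overlaps and gene assignments. A larger pseudocount did not apply to counts.

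Genes were named by a rule fixed before the data were examined. As no region passed, it gave the 5 with the smallest p in each direction among regions with a mean level at or above the median and the same direction in both replicate numbers, leaving out predicted genes and unplaced contigs. It added Gria2, Grin2a and Grin2b, and the 2 members with the smallest p in each direction of the other lists, of which a selection is given. A gene named by the rule is given by 1 region, the one with its smallest p. That value is not the value of the gene as a whole, and the comparisons can use different regions of a gene. The value of 1 gene that the rule names is not reported here. Genes outside the rule are said to have been chosen after their values were seen.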

Results

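H3K9me2 was profiled in the prefrontal cortex of 6 mice aged 5 to 6 months, with 2 mice in each of 3 groups, to ask how this repressive mark differs in FAD mice and under an EHMT1/2 inhibitor. ChIP libraries held 24.94 and 20.8 M reads in FAD, 24.49 and 26.58 M in WT and 20.45 and 22.0 M in FAD-BIX mice.

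The regions as called were mostly small and intergenic, and few were called in more than 1 library. A missing call does not show that a library had no signal there. In regions not called in a library, its median log2 ratio of ChIP to input was 0.71 (WT ChIP 2) to 1.12 (FAD ChIP 2). In the FAD versus WT table the median width was 329 bp, 72.3% of 33787 regions were centred between genes and 24.5% in introns, and 94.9% were called in 1 library alone. In the FAD-BIX versus FAD table these values were 325 bp, 71.9% of 43680 regions, 24.8% and 93.4%. Only 42 and 54 regions were called in all 4 ChIP libraries of a table. The X chromosome held 166 and 273 regions and the Y chromosome 7 and 14. FAD ChIP 2 had the most calls in both tables. In it 21849 regions of the first table were called, against 3904 in the ChIP library labelled FAD 1, 5867 and 4133 in the WT libraries, and 9753 and 11347 in the FAD-BIX libraries of the second table. It alone called 60.3% of the first table and 44.9% of the second.

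**Figure D1:**
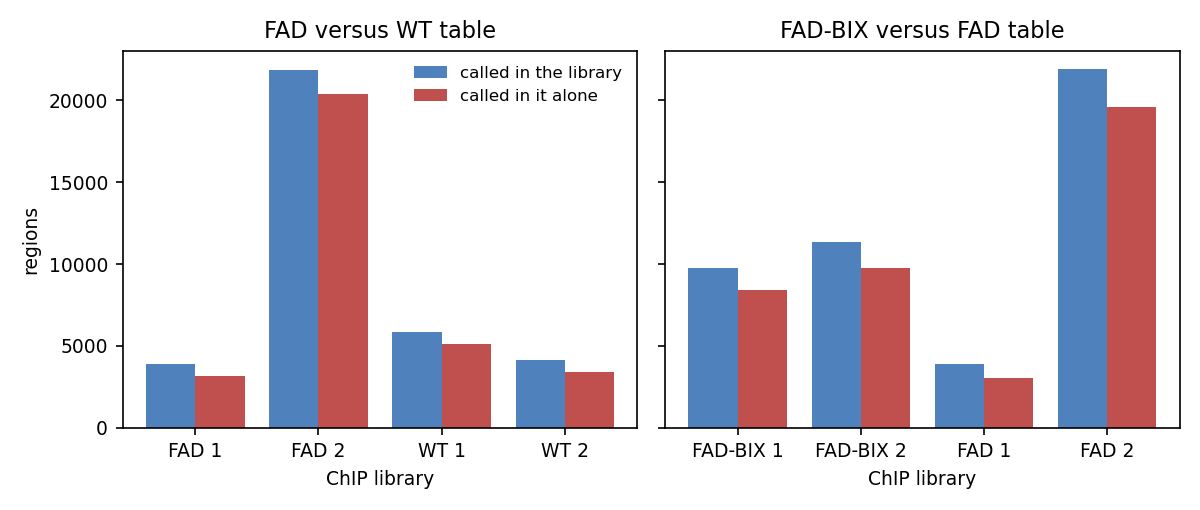
Number of regions called in each ChIP library (blue) and in that library alone (red) in the tables of FAD versus WT (left) and FAD-BIX versus FAD (right). FAD ChIP 2 stands at 21849 and 21930 regions, and each of the other libraries at 11347 or fewer.

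Reads at Thy1, a neuronal surface glycoprotein gene whose promoter is widely used to drive transgenes in neurons, separated the mice in ChIP and input alike. At chromosome 9, 44042078 to 44042390 (GRCm38), with its centre at -1150 bp from the nearest transcription start, FAD ChIP 2 held 40.3 RPM, while the ChIP library labelled FAD 1 held 0.16 and the WT libraries 0.20 and 0.08. The inputs held 24.1 in FAD 2 but 0.63 in the library labelled FAD 1, next to 0.08 and 0.69 in WT. In the intron region at 44042877 to 44045067, the FAD-BIX inputs held 183 and 94.4 RPM and FAD input 2 held 179, against 2.16 in the input labelled FAD 1. The input labelled FAD 1 was thus no higher than the higher WT input upstream of the gene. The ChIP library of that mouse enters every FAD direction in the text except those given without it. Thy1 was chosen after its values were seen.

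**Figure D2:**
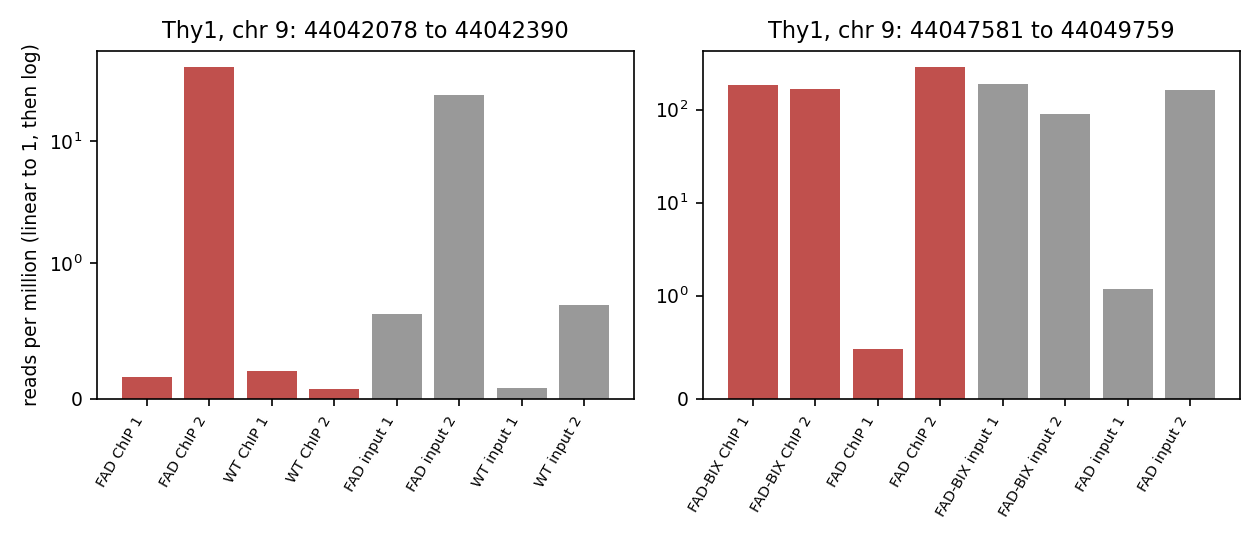
RPM in the Thy1 region upstream of the gene in the FAD versus WT table (left) and in the region at 44047581 to 44049759 in the FAD-BIX versus FAD table (right), 1 bar per library, ChIP in red and input in grey, on an axis that is linear up to 1 and logarithmic above. FAD 2 and both FAD-BIX mice lie far above the libraries labelled FAD 1, which hold 0.48 (ChIP) and 1.18 (input) in the right panel.

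Genes of heart muscle had high counts in the ChIP library labelled FAD 1. At Mb, which encodes myoglobin (chromosome 15, 77015493 to 77016074, UTR), it held 229 reads, against 9 in FAD ChIP 2 and 3 and 8 in WT. At Actc1, cardiac alpha-actin (chromosome 2, 114050266 to 114050686, exon), the counts were 219, 13, 6 and 6. At Nppa, atrial natriuretic peptide (chromosome 4, 148000770 to 148001379, UTR), they were 160 in the library labelled FAD 1, 4 in FAD ChIP 2, and 1 and 2 in FAD-BIX. The input labelled FAD 1 held 6, 17 and 7 reads at these regions. Mb, Nppa and this Actc1 region were chosen after their values were seen.

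**Figure D3:**
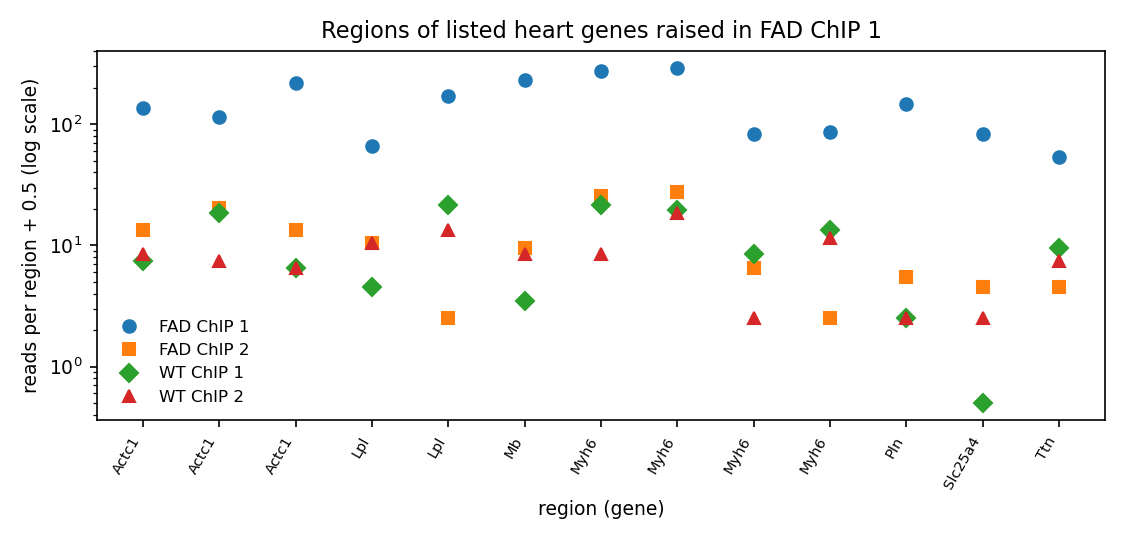
Reads plus 0.5 on a log axis in the 13 regions of listed heart genes that were at least 4 times higher in the ChIP library labelled FAD 1 than in the other ChIP libraries of the FAD versus WT table, 1 point per library. Counts in that library range from 53 to 293.

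Signal over input was present in all ChIP libraries. Over each table as a whole, much of which FAD ChIP 2 alone had called, it was highest in that library. The median log2 ratio of ChIP to input over the first table was 1.08 and 2.24 in FAD and 0.96 and 0.87 in WT, with group means of 1.66 and 0.91. Over the second table it was 1.11 and 1.51 in FAD-BIX, with group means of 1.31 in FAD-BIX and 1.56 in FAD. In the regions called in each library itself, FAD ChIP 2 was not the highest: the median was 2.54 there, 3.37 in the library labelled FAD 1, 2.46 and 2.50 in WT and 2.77 and 3.25 in FAD-BIX. In the regions not called in each library FAD ChIP 2 was the highest, with a median of 1.12, against 0.94 in the library labelled FAD 1, 0.76 and 0.71 in WT and 0.72 and 0.93 in FAD-BIX. Both sets were split by the calls of the same library, 21849 in FAD ChIP 2 but 3904 in the library labelled FAD 1. These medians therefore do not rank the libraries by enrichment. In regions called in the library labelled FAD 1 alone, its input had a median of 0 RPM. FAD-BIX input 2 also had a median of 0 RPM in the regions called in FAD-BIX ChIP 2 alone. The added count of 1 therefore weighs on the ratios of both libraries.

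FAD was compared with WT to find where the mark differs in the disease model. No region passed the test, and the values given are those of regions with the smallest p. Among regions with higher counts in FAD, an intron of Sntb1, a syntrophin of the dystrophin complex (chromosome 15, 55827403 to 55828123), held 27 and 41 reads in FAD and 7 and 7 in WT (log2 fold 1.83 ± 0.51, SE, n = 2 mice per group). Near Kcna4, a voltage-gated potassium channel (111740 bp from the transcription start), the log2 fold was 1.66 ± 0.54, and in Dip2c it was 1.47 ± 0.52. Near Il1f8, an interleukin-1 family gene, it was 1.61 ± 0.56. Myh6, the cardiac myosin heavy chain, stood at 3.22 ± 1.09, with 275 reads in the library labelled FAD 1 and 25 in FAD ChIP 2. Among regions with lower counts, an intron of Chil4, a chitinase-like gene (chromosome 3, 106209239 to 106209698), held 6 and 8 reads in FAD and 23 and 33 in WT (log2 fold -2.39 ± 0.53). An intron of Cntnap5a, a contactin-associated cell adhesion gene, stood at -2.05 ± 0.51. Regions between genes, given to Rbm24, Snx7 and Toporsl by the closest start, stood at -2.01 ± 0.52, -1.87 ± 0.52 and -1.67 ± 0.44. Their centres were at -46472, 109200 and -50845 bp from the nearest transcription start. Each of these 10 had an adjusted p of 0.832 in edgeR's quasi-likelihood test.

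Glutamate receptor genes held 133 regions in 9 ionotropic members. Of the 106 tested, 1 was higher and 4 lower at an unadjusted p under 0.05. Over all 27778 tested regions 255 were higher and 1381 lower at that p. A direction of more lower than higher regions in a list therefore follows the whole. With library totals as scaling the whole turned to 640 higher and 69 lower. An intron of Grid1 (chromosome 14, 35480706 to 35480999) held 3 and 2 reads in FAD and 12 and 25 in WT (log2 fold -3.18 ± 0.83), and an intron of Grik2, a kainate receptor, stood at -2.59 ± 0.72. In the NMDA receptor genes Grin2a (chromosome 16, 9785217 to 9785692, intron) and Grin2b (chromosome 6, 135812290 to 135812701, intron), the region with the smallest p stood at 0.70 ± 0.48 and -0.93 ± 0.53. No tested region was assigned to Gria2. In the metabotropic receptor Grm5 the log2 fold was 1.61 ± 0.71 and in Grm7 -2.00 ± 0.72, with 1 region higher and 1 lower in that list. Postsynaptic scaffold and adhesion genes held 348 regions, with 4 higher and 11 lower of the 283 tested, among them Cntnap2 (-2.53 ± 0.79) and Dlgap1 (2.06 ± 0.88). GABA receptor genes had 1 higher and 6 lower of 72 tested, such as Gabrb1 (-1.93 ± 0.62) and Gabrg3 (2.02 ± 0.74). Voltage-gated channels had 2 and 3, presynaptic genes 0 and 2 (Syt1, -1.82 ± 0.68), and activity-regulated genes 0 and 1 (Nr4a2, -2.06 ± 0.77). Cortical neuron markers had 0 and 2 (Sst, -1.56 ± 0.61), oligodendrocyte markers 0 and 1 (Ugt8a, -2.52 ± 0.78), and the microglia, astrocyte and endothelial lists 0 and 0. The regions given for Sst and Ugt8a lay between genes, at 42692 and 164975 bp from the nearest transcription start. Olfactory and vomeronasal receptors, the largest list with 736 regions, of which 619 were tested, had 3 and 17, zinc-finger genes 3 and 5, and ribosomal protein genes 0 and 2. The last were near the pseudogene Rpl9-ps1 and near Rps24. The H3K9 methylation, Alzheimer disease, protocadherin and Hox lists had 0 and 0, and no housekeeping gene had a region. None of the lists had a call over all regions or adjusted over the list alone, and of 15 lists tested by camera the smallest adjusted p was 0.982 (adjusted p = 0.994 with an estimated correlation). The median and the test differed in sign for voltage-gated channels, olfactory and vomeronasal receptors (mean only), endothelial markers and ribosomal protein genes, and the median and mean for microglia markers.

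Of 27778 regions tested, 0 passed an adjusted p of 0.05 by edgeR (smallest 0.832), with 255 higher and 1381 lower at an unadjusted p under 0.05. With no difference, 5% of the tested regions would be expected at that unadjusted p. DESeq2 also called 0, with 66 higher and 916 lower, and limma on ChIP over input called 0, with 1385 higher and 280 lower. The split depended on scaling: with library totals it was 640 higher and 69 lower, 2 regions passed, both in Myh6, and the median log2 fold of all regions moved from 0.01 to 0.64. That median was -0.06 without FAD ChIP 2 and 1.08 without the library labelled FAD 1. In simulated data with these counts, 0% of regions changed 2-fold, 1.5% of those changed 4-fold and 67% of those changed 8-fold were recovered. Without the library labelled FAD 1, 119 regions passed with TMM, 118 of them lower and the other at Thy1, and 12 passed with library totals, 11 of them lower. The split at an unadjusted p turned with the scaling there, from 56 higher and 3138 lower with TMM to 5978 higher and 379 lower with library totals. Without FAD ChIP 2, 21 passed with TMM and 24 with library totals, all higher and 12 of each in listed heart genes. Without either WT library, 0 passed with TMM and 1, at Thy1, with library totals. Among the 1731 tested regions called in at least 2 libraries, a set chosen after the values were seen, 7 passed, with adjusted p from 1.26e-05 to 0.0418 in edgeR, and 0 of them lay in listed heart genes or at Thy1. The 2 higher ones were between genes on the X chromosome, near Btbd35f29 and Gm21870. The sex of the mice is not given in the sources used here, so a difference of sex between the groups cannot be excluded there. The 5 lower ones lay on chromosome 8 (3 regions, 1 of them in Gm15319), 13 and 15. Those on chromosome 8 all lay between 20337730 and 20593687 and cannot be taken as independent. The region with the smallest p (chromosome 13, 108783582 to 108784104) held 212 and 40 reads in FAD and 849 and 190 in WT. There the library labelled FAD 1 held more reads than WT ChIP 2, and mice of 1 group differed widely. The test used ChIP counts alone, without the inputs. In the authors' deposited table, 902 regions had a p-value under 0.05, 722 higher and 180 lower in FAD, and the smallest q-value was 1. These were 2.67% of its regions, below the 5% expected at that p with no difference.

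In regions called in 1 library alone, levels were highest in that library. The choice of regions largely fixes this, so it is no result about the mice, and the levels of the other libraries are given beside it. In the 20360 regions called in FAD ChIP 2 alone, the median was 1.11 RPM in that library, 0.44 in the library labelled FAD 1, and 0.41 and 0.45 in WT. In the 5145 regions called in WT ChIP 1 alone, it was 0.86 in that library and 0.38 in WT ChIP 2, next to 0.36 in the library labelled FAD 1 and 0.43 in FAD ChIP 2.

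**Figure D4:**
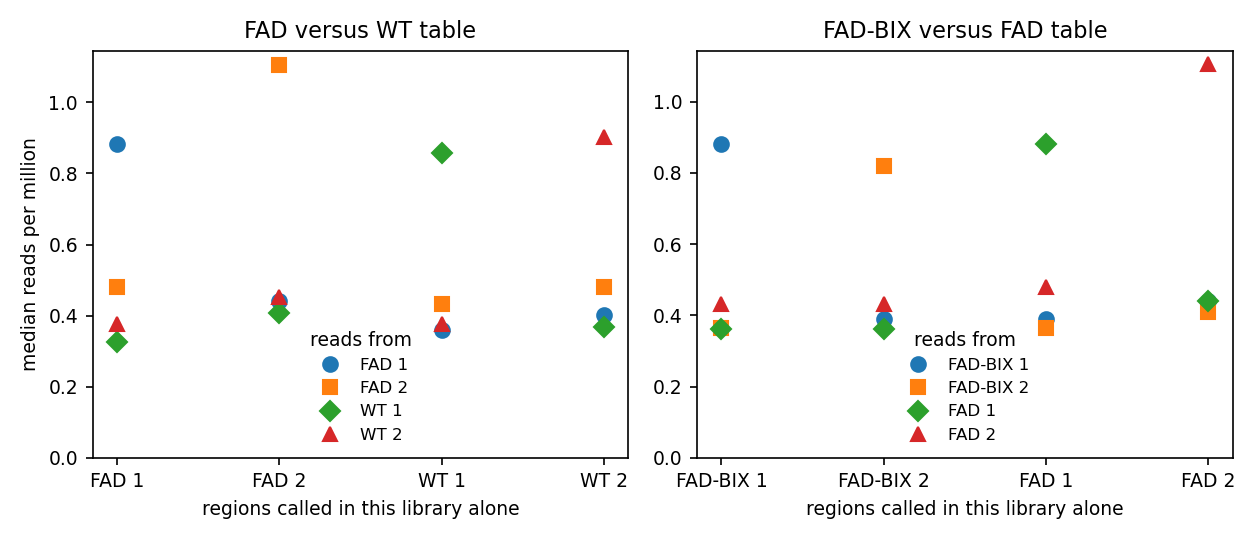
Median RPM of each ChIP library (symbols) in regions called in 1 library alone (horizontal axis), for the FAD versus WT table (left) and the FAD-BIX versus FAD table (right). Each library is highest in its own regions, for example 1.11 for FAD ChIP 2, which the choice of regions largely fixes. The other libraries lie between 0.33 and 0.48.

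FAD-BIX was compared with FAD to find where the mark differs under the inhibitor. No region passed here either. The test covers the called regions only, and relative scaling would not show a change of the mark shared by the whole genome. Among regions with higher counts in FAD-BIX, a region near Cbln2, a synapse organizer (chromosome 18, 86947250 to 86947860), held 29 and 30 reads in FAD-BIX and 8 and 16 in FAD (log2 fold 1.74 ± 0.52). An intron of Syndig1, which encodes an AMPA receptor-associated protein, stood at 1.86 ± 0.56, Ralyl at 1.94 ± 0.59, Tspyl5 at 1.93 ± 0.59 and a region near Kif18a, a kinesin, at 1.99 ± 0.57. The regions given for Cbln2 and Kif18a lay between genes, at 235490 and 88863 bp from the nearest transcription start. Among those with lower counts, an intron of Zfhx3, a homeobox transcription factor (chromosome 8, 108529434 to 108530506), held 9 and 14 reads in FAD-BIX and 38 and 57 in FAD (log2 fold -1.60 ± 0.49). Fut9, a fucosyltransferase, stood at -2.04 ± 0.63 and the natriuretic peptide gene Nppb at -1.89 ± 0.60. The heart genes Myh6 (-3.61 ± 0.79) and Actc1 (-3.36 ± 0.77) had 293 and 115 reads in the library labelled FAD 1 and 27 and 20 in FAD ChIP 2. All 10 had an adjusted p of 0.897 in edgeR's quasi-likelihood test.

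Ionotropic glutamate receptor genes held 174 regions in 10 members. Of the 137 tested, 6 were higher and 2 lower in FAD-BIX at an unadjusted p under 0.05. Over all 31055 tested regions 1221 were higher and 365 lower at that p. A direction of more higher than lower regions in a list therefore follows the whole. With library totals as scaling the whole turned to 137 higher and 456 lower. An intron of the AMPA receptor gene Gria1 held 25 and 25 reads in FAD-BIX and 12 and 16 in FAD, and an intron of Grid1 held 3 and 8 in FAD-BIX and 13 and 34 in FAD (log2 fold -1.59 ± 0.73). A region near Grin2a (chromosome 16, 9557359 to 9557668) held 17 and 10 reads in FAD-BIX and 2 and 3 in FAD (log2 fold 2.80 ± 1.21), and an intron of Grin2b (chromosome 6, 135843580 to 135843846) stood at 1.46 ± 0.78. The regions given for Grid1, Grin2a and Grin2b are not those given for FAD versus WT, so their signs cannot be set against each other. No tested region was assigned to Gria2. Metabotropic receptors had 10 higher and 0 lower of 67 tested (Grm7, 1.85 ± 0.66). Postsynaptic genes had 9 and 0 of 334 (Cdh12, 1.26 ± 0.45), and GABA receptor genes 10 and 0 of 91 (Gabra6, 1.92 ± 0.62). In the metabotropic and GABA lists the share of higher regions was well above that of the whole. These lists did not pass camera (adjusted p 0.496 and 0.847), and regions of 1 gene are not independent. Voltage-gated channels had 7 and 1 (Kcnb2, 1.43 ± 0.51, and the lower Cacna2d1, with 4 and 2 reads in FAD-BIX and 14 and 23 in FAD), presynaptic genes 2 and 0, activity-regulated genes 1 and 0 (Bdnf, 1.77 ± 0.64), and cortical neuron markers 2 and 1 (Tbr1, 3.05 ± 0.99, and Rbfox1, -1.33 ± 0.56). The regions given for Gabra6, Tbr1 and Rbfox1 lay between genes, at 17155, 33075 and -494557 bp from the nearest transcription start. Endothelial markers had 1 and 0, microglia markers 0 and 1 and protocadherins 0 and 1. The microglia region was Lpl, which held 169 reads in the library labelled FAD 1 and 2 in FAD ChIP 2; it was the sole call adjusted over the list alone. Olfactory and vomeronasal receptors had 22 and 9, zinc-finger genes 5 and 3, and ribosomal protein genes 1 and 0, near the pseudogene Rpl7a-ps3. The last list was made by symbol prefix and also took in kinase genes such as Rps6ka1 and Rps6ka5. The astrocyte, oligodendrocyte, H3K9 methylation, Alzheimer disease and Hox lists had 0 and 0, and no housekeeping gene had a region. None of 17 lists passed camera: the smallest adjusted p was 0.151, for clustered protocadherins (5 genes, median log2 fold -0.81), with adjusted p = 0.796 with an estimated correlation. The median differed in sign from the test for GABA receptor genes, astrocyte markers, cortical neuron markers and zinc-finger genes.

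Of 31055 regions tested, 0 passed by edgeR (smallest adjusted p 0.897), with 1221 higher and 365 lower at an unadjusted p under 0.05, and DESeq2 called 0, with 711 and 141, and limma on ChIP over input 0, with 394 and 689. With library totals as scaling the split was 137 higher and 456 lower and 4 regions passed, 3 of them in listed heart genes. The median log2 fold then moved from 0.03 to -0.34, and was 0.34 without FAD ChIP 2 and -0.57 without the library labelled FAD 1. The other region that passed, at chromosome 9, 78175341 to 78175620, was chosen after its values were seen and held 222 reads in FAD-BIX ChIP 2, 2 in FAD-BIX ChIP 1, 14 in the library labelled FAD 1 and 0 in FAD ChIP 2. In simulated data, 0%, 6.5% and 56% of regions changed 2-fold, 4-fold and 8-fold were recovered. Without the library labelled FAD 1, 26 regions passed with TMM, 25 of them higher, and 17 with library totals, 9 of them higher. The split at an unadjusted p was 1786 higher and 79 lower with TMM and 330 higher and 3238 lower with library totals. Without FAD ChIP 2, 23 and 18 passed, of which 13 of each lay in listed heart genes and 3 of each at Thy1. Without FAD-BIX ChIP 1 or 2, 16 and 12 passed with TMM, of which 11 and 9 lay in listed heart genes, and 0 and 0 passed with library totals. With no filter on low counts 17 passed, 13 of them in listed heart genes and 2 at Thy1. In the authors' deposited table, 912 regions had a p-value under 0.05, 340 higher and 572 lower in FAD-BIX. These were 2.09% of its regions, again below the expected 5%.

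Whether the inhibitor moved regions in the direction opposite to the FAD difference was examined in 18221 regions matched between the tables and tested in both. Across these regions, which are not independent replicates, the log2 folds of FAD over WT and of FAD-BIX over FAD had a correlation of -0.475, and 70.9% of regions had opposite signs. Simulated unchanged groups that shared the FAD libraries gave -0.477 ± 0.0059 (SD of 20 data sets) and 66.0% ± 0.24, so the share of opposite signs was above the simulated one by more than its spread, while the correlation was within it. The covariance was -0.124, against -0.181 ± 0.0034 in the simulation, so the simulated variation did not match the data. The simulation also did not repeat the selection of regions, many of them called in FAD ChIP 2 alone. The higher share of opposite signs therefore cannot be read as a reversal by the inhibitor. With 1 FAD library in each fold, so that none was shared, the correlation was 0.05 with the library labelled FAD 1 against WT and 0.06 with FAD ChIP 2 against WT, and 54.8% and 53.2% of regions had opposite signs. There were no called regions whose overlap or distribution over chromosomes and annotation classes could be tested.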

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

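All tests in this part were chosen after the result was seen. FAD input 2 held 24.1 RPM upstream of Thy1 at chromosome 9, 44042078 to 44042390, in a library the comparisons use only as background, 34.7 times the higher of the WT inputs.

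A change of H3K9me2 is argued against as the whole source of the Thy1 pattern, since the input, which has no immunoprecipitation, shows it with a ratio of 34.7. A swap between the mouse labelled FAD 1 and a WT mouse is argued against too, because the higher WT input held 1.1 times the RPM of the input labelled FAD 1, and neither WT mouse had raised reads. A candidate explanation is that the mouse labelled FAD 1 lacks the extra Thy1 copies of the other FAD mice: its input held 0.905 times the RPM of the higher WT input. A single wrong label, a mouse that did not inherit the transgene and a mouse of another line all stay open, and none of these data separate them.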

How the results depend on the processing

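The alternatives that keep regions called in at least 2 libraries or not called in FAD ChIP 2, that leave a library out with library totals, and that share no FAD library were chosen after seeing the data. With all libraries, the count of 0 was kept under 7 of 10 alternatives in each comparison, not counting stricter thresholds, which cannot add calls. Library totals gave 2 and 4 calls, and no filter gave 17 for FAD-BIX versus FAD. Regions called in at least 2 libraries gave 7 for FAD versus WT, 2 higher and 5 lower and 0 of them in listed heart genes or at Thy1, and regions not called in FAD ChIP 2 gave 5 and 8, of which 5 and 7 lay in listed heart genes. Leaving out 1 ChIP library gave 0 to 119 calls for FAD versus WT and 12 to 26 for FAD-BIX versus FAD with TMM, and with library totals 12 and 24 without FAD 1 and 2, 1 and 1 without WT 1 and 2, then 17 and 18 without FAD 1 and 2 and 0 and 0 without FAD-BIX 1 and 2; the lone library of a group is then assumed to vary like the others, and the libraries responsible are named with the results. The replicate block gave 0 calls in both comparisons. The deviations of same-numbered libraries had correlations of 0.06 and -0.04 over the tested regions. Counting error at 11 to 20 reads per region weighs on these correlations, so they cannot exclude a batch shared by number. The numbers were not taken as pairing in the main test. The median log2 fold with library totals, 0.64 for FAD versus WT, was 0.008 with TMM and -0.06 to 1.08 with 1 library left out, the lowest without FAD ChIP 2. For FAD-BIX versus FAD it was -0.34, and -0.57 to 0.34 with 1 library left out, the highest without FAD ChIP 2. The correlation between comparisons was -0.484 with 1 bp overlap, -0.466 with 80% reciprocal overlap, and 0.05 and 0.061 with no shared library, where the sharing itself is removed. No list passed under any alternative of the list test. In the authors' deposited table a 10 times smaller p left 80 and 78 regions. No value could be had for called regions alone in the correlation, or for the distribution of called regions at a stricter threshold, as none passed. Causes were not tested except where named. A median of 11 to 20 reads per region limits what could be detected.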

Other observations

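All tests in this part were chosen after the result was seen. Among regions called in all 4 ChIP libraries of a table, the highest with a named gene in both tables was near Sfi1, a centrosome gene (chromosome 11, 3192989 to 3195244), with 91.5 ± 27.2 RPM in ChIP and 53.6 ± 14.6 in input (SD, n = 4 libraries of 2 groups, FAD versus WT table). A region near the vomeronasal receptor Vmn1r238 (chromosome 18, 3116696 to 3120621) held 22.3 ± 8.58 in ChIP and 4.22 ± 2.01 in input, and one near Nwd1 held 20.2 ± 2.53 and 4.59 ± 0.908. Regions centred in last exons made up 3.0% of those called in at least 2 libraries and 2.0% of those called in 1 (Fisher's exact test, adjusted p = 0.0334), and 3.23% against 2.01% in the FAD-BIX versus FAD table (adjusted p = 0.000182). Olfactory and vomeronasal receptors made up 7.81% and 5.68% of the regions with a gene, which did not pass (adjusted p = 0.359). Regions of 1 chromosome are not independent.

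FAD ChIP 2 called over 5 times as many regions as the library labelled FAD 1. A different read type or mapping of FAD ChIP 2 stays open. Its median ratio to the library labelled FAD 1 was 0.621 in 28 regions high in WT input 1 and low in WT input 2, between the bounds set for either answer, and 0.936 in 66 regions high in FAD-BIX input 2 and low in FAD-BIX input 1, above the bound set against this explanation, while FAD input 2 stood at 0.406 and 0.453 of the input labelled FAD 1. In the opposite choices, where such a difference would raise the ratio, it was 1.73 (37 regions) and 1.71 (145 regions), but the inputs gave 1.16 and 0.964. More H3K9me2 in FAD mice at the regions called in FAD ChIP 2 alone cannot be told apart from the rest, since the library labelled FAD 1 was the highest of the other libraries in 37.9% of them, WT ChIP 2 in 36.4% and WT ChIP 1 in 25.7%, and the label of FAD 1 is in doubt.

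In the ChIP library labelled FAD 1, 26 regions were at least 4 times higher than in the other libraries of the FAD versus WT table, and 57.7% of them were centred in exons or UTRs, against 6.22% of 1688 others with at least 30 reads. Such a share would be seen with reads from heart transcripts (Fisher's exact test, p = 8.13e-12). Of the 26 regions, however, 13 lay in 7 listed heart genes, so the test is not of heart genes alone. Several lay in the same gene, such as Myh6 and Actc1, and all were raised in 1 library. The p-value takes them as independent, which they are not. Of 35 listed heart genes, 10 had a region and 7 were raised, but the list was written after several had been seen, Lpl is also in the microglia list, and expression of these genes in cortex was not analysed here. A gain of H3K9me2 in FAD mice at these genes stays open: the median of FAD ChIP 2 was 1.93 times the WT mean there, but the regions were chosen as higher in the library labelled FAD 1 than in FAD ChIP 2, so this value does not decide it. The source of such reads in a cortex library was not tested.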
